A study of Mus musculus with 8 samples.

How the data were processed

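Single-cell RNA was measured in 8 HIVE libraries of mouse bone marrow cultured with M-CSF, 4 without and 4 with CYR61. The deposited tables hold counts per gene and cell barcode, and the submitters' processing notes give the genome build mm10. The aligner, the counter, the annotation and the rule for calling cells are not given in the sources used here. The values were whole numbers from 0 up. Each table listed 5000 barcodes of 12 bases, down to barcodes with very few counts, so no cell call by the authors was taken as given. Total counts per library ranged from 1379637 to 16318946. Groups and replicate numbers were taken from the labels.

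A barcode was kept as a cell with at least 300 detected genes and at most 20% of UMIs from mitochondrially encoded genes. This kept 12848 of 40000 barcodes and dropped 1399 others for their mitochondrial share. Scrublet, run per library, marked 67 of the kept cells (0.521%) as doublets, and they were left in. Cells were normalized, reduced to 30 principal components of 2000 variable genes and clustered with the Leiden method at resolution 0.5 on 15 neighbours, in Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0 and igraph 0.11.9. Clusters were named from marker genes. Another class needed at least 3 of its markers, and more than the macrophage class had, at 2-fold or more over the other cells and detected in at least 10% of the cluster. The rest were macrophage- and monocyte-like with at least 3 markers of either type in 25% of their cells. Of the 8 clusters, 1 was neutrophil-like, 1 megakaryocyte-like or platelet-like, and the rest macrophage- or monocyte-like. Y-linked genes led 2 macrophage-like clusters, Xist was among the leading genes of another, ribosomal RNA led the largest and cell cycle genes led 1. Clusters were therefore pooled into classes before shares were compared.

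Counts were summed over the kept cells of each library. Gene tests used edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr and the quasi-likelihood test with the protein as the sole term, and Benjamini-Hochberg adjusted p under 0.05. All libraries entered each fit. DESeq2 1.42.0 was run beside it. The same test was made in macrophage- and monocyte-like cells. No other class had 20 cells in every library, so no other class and no difference between classes was tested. The difference of the effect between the date stamps was tested as an interaction. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 3 measured members, and again with an estimated correlation and with fry. Shares of cells and measures of depth were compared with exact two-sided permutation tests over all 70 assignments, whose smallest p is 0.0286, in scipy 1.17.1. Shares of single libraries carry 95% Wilson intervals. Ratios of genes with 1 to 3 control counts pool the counts of each group over its total. A count of 0 was given a floor of 3 counts over the group, and intervals and floors cover counting error alone. These tests, the gene lists, the cell markers, the naming rule and most alternatives were chosen before the data were examined.

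The naming rule applied to each fit of all cells or macrophage-like cells. Among genes with adjusted p under 0.05, non-overlapping groups and a mean of at least 20 CPM in the higher group, it named the 10 with the largest increase and the 10 with the largest decrease, or all where fewer passed. It left out gene models with Gm and a number, names ending in Rik, and mt-, Rpl and Rps genes. Ccn1, Pdgfa, Pdgfb, Syk, Nfkb1, Rela, Irak4, Itgam, Itgb3 and Tlr4 were added by purpose, up to 4 called members of each list with the smallest p in each direction, and the 5 genes with the smallest p of an interaction. Genes outside the rule were named where a count was 5 or lower, and the text says so. Gene positions are those of the GENCODE vM21 annotation on mm10.

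The lists covered PDGF ligands and receptors, SYK and ITAM signalling, NF-kB, inflammatory cytokines and enzymes, chemokines, type I interferon response, MHC class I and class II, alternative activation and fibrosis-associated macrophage genes. They also covered inflammatory monocytes, mature macrophages, integrins and other CCN1-binding proteins, YAP and TEAD targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, LXR targets, lysosome and proliferation. Lists of immediate early genes, unfolded protein response, NRF2 targets, iron handling, osteoclasts, ribosomal proteins and mitochondrially encoded genes completed the set, beside the markers of each cell class.

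Home-library cells were added after the data were seen, because barcodes recurred between libraries of a date. A barcode listed in several tables of a date was kept where it had most UMIs, whatever the group. The rule set beforehand for summing tables as runs of the same library was not met. The same edgeR test, naming rule and lists were applied to these cells. The interferon score, the mean log2 CPM of the interferon list, and the split of the libraries by Xist and Y-linked counts were added at the same point.

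Alternatives left out each library in turn, added the replicate number or the date as a term, used each date alone, or changed the scaling, the gene filter, the cell filter, the doublet rule or the clustering resolution. Others thinned each cell to 500 UMIs. For home-library cells, further alternatives added the Xist and Y split as a block, used the Xist or the Y libraries alone, kept barcodes of a single table, left out ribosomal RNA, or took 283 cells per library thinned to 500 UMIs.

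The tests were tried on simulated data with 50 genes changed at each fold size. For all kept cells, over 10812 genes, the test recovered 4% of genes changed 1.5-fold, 16% at 2-fold, 70% at 4-fold and 86% at 8-fold, with 5 false calls among 93. For macrophage-like cells, over 10802 genes, it recovered 2%, 24%, 78% and 92%, with 8 false calls among 106. For home-library cells, over 10111 genes, it recovered 0%, 12%, 74% and 90%, with 2 false calls among 90. A planted list of 30 genes changed 1.5-fold was found by camera in all 3 sets of counts, and 1 other list was called in the home-library set. The simulated genes were drawn independently, without correlation between genes, a split of the libraries or shared barcodes. The simulation therefore cannot show how camera with the preset correlation behaves on the real counts.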

Results

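The series measured single-cell RNA in mouse macrophages exposed to CYR61, a matricellular protein that binds integrins and is encoded by Ccn1. Bone marrow of C57Bl/6J mice, labelled male and 10 weeks old, was cultured for 3 days with the growth factor M-CSF and then for 24 h with or without 4 µg/mL of the protein. Libraries were made with the HIVE microwell platform, which captures single cells in an array and tags each molecule. There were 4 control libraries and 4 CYR61 libraries. The labels do not say whether replicates were separate animals or separate cultures, so p-values of gene tests and permutation tests below measure the spread between libraries. Camera with its preset correlation of 0.01 instead compares list genes with other genes. Its very small p-values rest on that assumed correlation and not on the spread between libraries alone. The series title names CYR61, liver fibrosis and SYK, NF-kB and PDGF signalling in monocyte-derived macrophages, and the comparison asks which genes the added protein moved.

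Each count table listed 5000 barcodes, and together they listed 32249 genes. The total UMI count was 4098787, 5468740, 1379637 and 2167067 in control replicates 1 to 4, and 10465018, 16318946, 2105422 and 4781702 in CYR61 replicates 1 to 4. Kept cells had at least 300 detected genes and at most 20% mitochondrial UMIs. They numbered 1094, 2135, 491 and 498 in the control libraries and 2795, 4110, 634 and 1091 in the CYR61 libraries. The median cell held 821 to 1779 UMIs. CYR61 libraries had 2157.5 ± 1599.7 kept cells and control libraries 1054.5 ± 773.8 (SD, n = 4 each), a difference within the spread between libraries (exact two-sided permutation p = 0.229, adjusted p = 0.686). Total UMIs of kept cells, median UMIs, median genes, mitochondrial share and ribosomal RNA share also overlapped between the groups (adjusted p from 0.686 to 0.886, exact two-sided permutation tests, n = 4).

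Many barcodes were listed in more than 1 library of the same date stamp. Replicates 1 and 2 of both groups carried the earlier stamp, and replicates 3 and 4 the later one. Of 1804 deep barcodes, with at least 5000 UMIs, 1657 (91.9%) were also listed in another library of the same date, and 4 (0.222%) in a library of the other date. In control replicate 2, 75.5% of the UMIs of kept cells belonged to barcodes that had more UMIs in a CYR61 library. The same share was 25.1% in control replicate 4, 20.3% in control replicate 3 and 0.448% in control replicate 1. In CYR61 replicate 3, 21.8% of UMIs belonged to barcodes with more UMIs in a control library. Libraries of the same group shared barcodes too. Barcodes with more UMIs in another CYR61 library held 13.3% of UMIs in CYR61 replicate 1 and 8.60% in CYR61 replicate 2. In kept cells these libraries were thus not fully separate, and the spread between them may be understated. A second set of cells, called home-library cells, was therefore defined after the data were seen. It kept each barcode only in the library of its date where it had most UMIs, and it held 9196 of the 12848 kept cells. The home-library cells numbered 1058, 315, 294 and 390 in the control libraries and 1971, 3604, 499 and 1065 in the CYR61 libraries (1784.75 ± 1355.9 against 514.25 ± 364.8, exact permutation p = 0.0571, adjusted p = 0.171, n = 4).

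**Figure D1:**
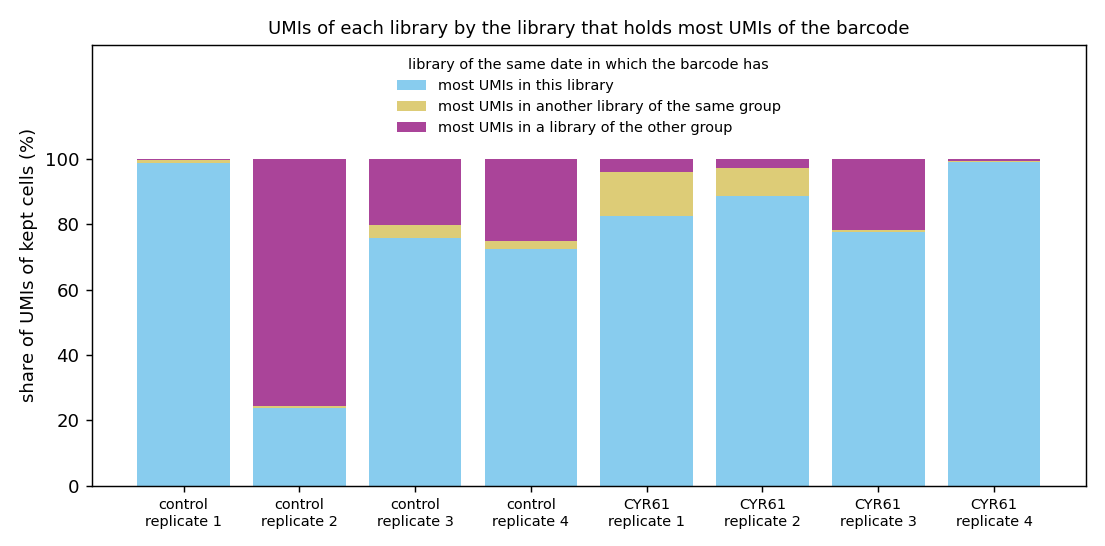
Share of the UMIs of kept cells in each library (vertical axis, percent) by the library of the same date that held most UMIs of the barcode. Barcodes with more UMIs in a library of the other group made up 75.5% of the UMIs of control replicate 2 and 0.560% of those of CYR61 replicate 4.

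The libraries also split by X-linked and Y-linked RNA, against labels that call every animal male. Xist is the RNA that silences the second X chromosome and is normally transcribed in female cells. In home-library cells it reached 1249 and 1213 CPM, UMI counts scaled to a common library total, in control replicates 2 and 3, and 1206 and 1152 CPM in CYR61 replicates 1 and 2. Y-linked genes summed to 387 and 323 CPM in control replicates 1 and 4 and to 399 and 385 CPM in CYR61 replicates 3 and 4, where Xist was at most 1.16 CPM. Each group thus held a pair of Xist libraries and a pair of Y libraries. This split is used below as a technical block and not as a comparison of the study.

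**Figure D2:**
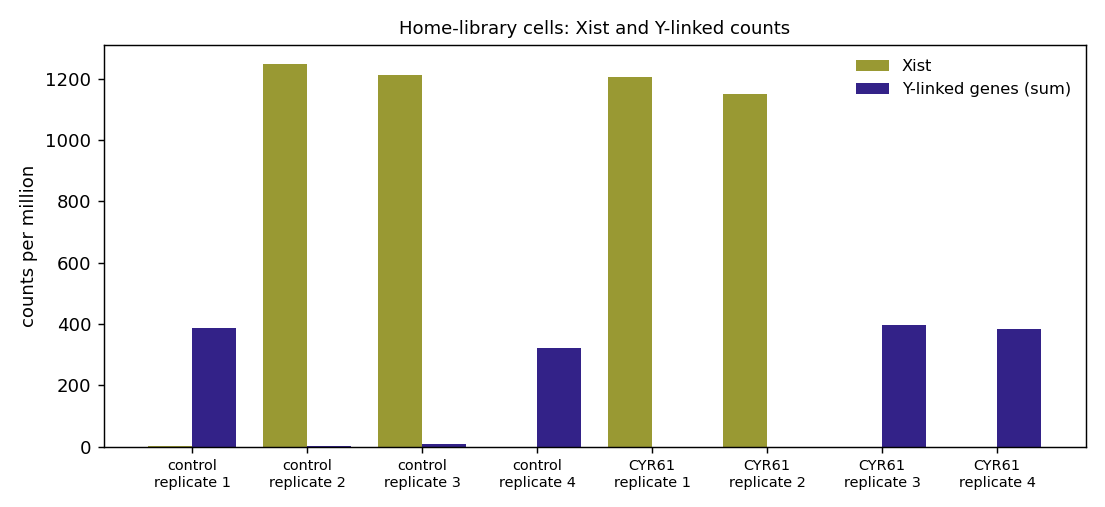
Xist and the sum of Y-linked genes in home-library cells (vertical axis, CPM) for the 4 control and 4 CYR61 libraries. Xist bars reach 1152 to 1249 CPM in 4 libraries, and the other 4 carry Y-linked counts of 323 to 399 CPM.

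The share of each cell class asked whether the protein changed the makeup of the culture. Nearly all cells resembled macrophages or monocytes, and commonly expressed Csf1r, Adgre1 and Cd68, which encode the M-CSF receptor, the F4/80 surface protein and a lysosomal glycoprotein. A cluster of 144 cells led by Ngp, Ltf and Camp, which encode neutrophil granule proteins, was neutrophil-like. A cluster of 18 cells with Ppbp and Itga2b, a platelet chemokine and a platelet integrin, was megakaryocyte-like or platelet-like. Macrophage- and monocyte-like cells made up 98.7% ± 0.541 of control cells and 97.5% ± 3.17 of CYR61 cells (SD, n = 4, adjusted p = 0.857, exact two-sided permutation test). Neutrophil-like cells made up 1.14% ± 0.444 and 2.40% ± 3.15 (exact permutation p = 0.857, n = 4). That CYR61 mean rested on replicate 3, in which 45 of 634 cells were neutrophil-like (7.10%, 95% Wilson interval 5.35% to 9.37%), and without it the difference was -0.308 percentage points. Megakaryocyte-like cells were at most 0.402% of any library (exact permutation p = 0.743, n = 4). No class passed. These counts and shares are of kept cells. In control replicate 2, 1789 of 2135 kept cells had more UMIs in a CYR61 library, so the groups were not separate. In home-library cells, macrophage-like cells made up 98.7% ± 0.483 of control and 97.2% ± 3.89 of CYR61 cells. Neutrophil-like cells made up 1.12% ± 0.321 and 2.76% ± 3.91, and megakaryocyte-like cells 0.208% ± 0.253 and 0.0416% ± 0.0832. No class passed there (adjusted p = 0.914 each, exact permutation tests, n = 4).

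In all kept cells, edgeR called no single gene. The fixed type I interferon list, of antiviral effectors and regulators of the interferon response, passed camera upward (adjusted p = 1.36e-44). It did not pass at an adjusted p = 0.190 with an estimated correlation, or with fry (adjusted p = 0.169). All 34 members had a positive log2 fold change, with a median of 1.51. Their mean log2 CPM per library was 6.86 ± 0.417 in CYR61 libraries and 5.17 ± 1.15 in control libraries (SD, n = 4). Every CYR61 library lay above every control library, and the exact two-sided permutation p of 0.0286 is the smallest that 70 assignments can give. This score was chosen after the data were seen. The lowest control was replicate 1, at 3.52, and the other controls lay between 5.46 and 6.18. In control replicate 1, 0.448% of UMIs belonged to barcodes with more UMIs in a CYR61 library, against 20.3% to 75.5% in the other controls. In home-library cells all controls lay between 3.20 and 3.67, close to replicate 1. In all kept cells, none of the 34 genes passed over all genes tested and 32 passed when adjusted over the list alone.

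The edgeR quasi-likelihood test of all kept cells called 0 of 11148 genes, with 279 genes at an unadjusted p under 0.05 (185 higher and 94 lower with CYR61). Most alternatives also had more genes higher than lower, but not all. Without CYR61 replicate 3 there were 185 higher and 318 lower, and with the date as a term 248 and 291. In the earlier date alone there were 70 higher and 505 lower, and without a gene filter 401 and 1036. DESeq2 called 1 gene, C1qa, which encodes a chain of the complement protein C1q. It was named after its values were seen, with 83.7 ± 12.2 CPM in CYR61 libraries and 39.1 ± 7.63 CPM in control libraries (log2 fold change 1.10 in DESeq2, adjusted p = 0.00493, n = 4). The groups did not overlap for 231 genes, or 2.07% of those tested, where chance gives 2.86%. In the macrophage- and monocyte-like cells, edgeR called 0 of 11140 genes, with 293 at an unadjusted p under 0.05. DESeq2 called 2 there, C1qa and Ly6e, an interferon-inducible surface protein. They were also named after their values were seen (log2 fold changes 1.10 and 1.55, adjusted p = 0.00438 and 0.0492). Without control replicate 2, edgeR called 5 genes in this class. These were Ddx58 and Oas2, sensors of viral RNA, Fcgr1, a receptor for antibodies, Gbp2, a guanylate-binding protein, and Herc6, a ligase for the modifier ISG15. All 5 were higher with CYR61 and were named after their values were seen.

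The effect of the protein was also compared between the dates, a technical split. Both CYR61 libraries of the earlier date were Xist libraries, and both of the later date were Y libraries. Each date held a control of each kind, so a difference between dates cannot be told apart from that split. At the earlier date, 75.5% of the UMIs of control replicate 2 also belonged to barcodes with more UMIs in a CYR61 library. In all kept cells the edgeR interaction test called 0 of 11148 genes, with 573 at an unadjusted p under 0.05, and DESeq2 was not run for it. By the naming rule, the genes with the smallest p were Mcemp1, a mast cell surface protein, Trim25, a ubiquitin ligase of antiviral sensing, Ddx3y, a Y-linked helicase, Fgl2, a prothrombinase, and Etv5, a transcription factor. None of them passed (edgeR adjusted p = 0.805). Within each date, with a pair of libraries per group, the interferon list had a median log2 fold change of 1.08 at the earlier and 1.72 at the later date. At the earlier date edgeR called 0 genes, with 575 at an unadjusted p under 0.05 (70 higher and 505 lower with CYR61). At the later date it called 52 genes up, 23 of them in the interferon list, and 4 down. Those down, named after their values were seen, were Xist, Cd28, which encodes a T cell costimulator, and the gene models Gm12792 and Gm20594. In kept cells of the later date, Xist was 924 CPM in control replicate 3 and at most 20.3 CPM in the other libraries.

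In home-library cells, which were defined after the data were seen, edgeR called 121 of 10422 genes. With CYR61, 117 rose and 4 fell, and the groups did not overlap for any of these 121 genes. Of the 117 that rose, 33 were in the fixed interferon list, 17 in other lists alone and 67 in no list, a count chosen after the result was seen. The fixed list does not hold every interferon-inducible gene, so absence from it does not place a gene outside the interferon response. At an unadjusted p under 0.05 there were 646 genes. Non-overlapping groups occurred for 527 genes, or 5.06%, where chance gives 2.86%. DESeq2 called 159 genes up and 25 down. With the Xist and Y split as a block, 199 rose and 32 fell.

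The largest increases by the naming rule were in genes near silence in the control libraries. Ifi213, a member of the family of nuclear DNA sensors with pyrin and HIN domains (chromosome 1, 173566283 to 173599274), had 0 control counts and 65.4 ± 40.6 CPM with CYR61. This was at least 86.8-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00134, n = 4). Its neighbour Ifi206 (chromosome 1, 173468485 to 173491041) had 1 control count and 65.3 ± 44.9 CPM with CYR61, a ratio of 256 with a counting interval of 45.9 to 10129. Ms4a4c, a membrane-spanning protein of inflammatory monocytes (chromosome 19, 11404770 to 11427246), had 3 control counts and 114 ± 97.2 CPM with CYR61, a ratio of 123 (42.2 to 599). Ifi44, an interferon-induced cytoplasmic protein (chromosome 3, 151730922 to 151749960), had 3 control counts and 76.2 ± 54.7 CPM, a ratio of 98.6 (33.6 to 479). Acod1, which encodes the enzyme that makes itaconate in activated macrophages (chromosome 14, 103046977 to 103056573), had 1 control count and 32.2 ± 28.1 CPM, a ratio of 108 (19.2 to 4257). These ratios and the bound for Ifi213, like those of low-count genes below, pool the counts of a group over its summed total. They are therefore weighted by depth, mostly toward CYR61 replicates 1 and 2, and differ from ratios of the mean CPM. The edgeR adjusted p of the last 4 genes lay between 0.000349 and 0.00625.

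The Ifit genes, which encode proteins that bind foreign RNA, sit in a cluster on chromosome 19. Ifit3 (34583531 to 34588731) rose from 1.56 ± 2.27 to 141 ± 65.8 CPM (log2 fold change 6.34, SE 0.60, edgeR adjusted p = 0.000155, n = 4). Ifit2 (34550694 to 34576419) rose from 14.98 ± 9.79 to 837 ± 513 CPM (log2 fold change 5.91, SE 0.58, edgeR adjusted p = 0.000177, n = 4). Ifit1 (34640871 to 34650009) rose from 1.51 ± 1.73 to 111 ± 29.4 CPM, a log2 fold change of 5.63. Ifit3b (34607970 to 34613401) had 2 control counts and 21.2 ± 6.70 CPM with CYR61, a ratio of 54.8 (15.1 to 454). Mx1, a GTPase that blocks influenza viruses (chromosome 16, 97447035 to 97462907), rose from 2.05 ± 1.54 to 129 ± 70.2 CPM, a log2 fold change of 5.61. How the counts treated reads shared between close relatives is not known, so values of single Ifit, Ifi200, Slfn, Oas and Ms4a genes are uncertain between members.

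The 4 genes that fell did so with less margin. Ighm, the heavy chain of IgM and a B cell gene (chromosome 12, 113418558 to 113422730), was 23.9 ± 11.4 CPM in control and 3.31 ± 1.69 CPM in CYR61 libraries (log2 fold change -2.72, SE 0.51, edgeR adjusted p = 0.0196, n = 4). Gclc, the enzyme that limits glutathione synthesis (chromosome 9, 77754535 to 77794485), fell from 102 ± 15.2 to 51.4 ± 7.51 CPM (log2 fold change -0.96, SE 0.20, edgeR adjusted p = 0.0344). Ifi27, a mitochondrial protein (chromosome 12, 103434211 to 103440239), fell from 124 ± 20.5 to 67.0 ± 9.19 CPM (log2 fold change -0.88, SE 0.19, edgeR adjusted p = 0.0476). Gclc passed in 11 of 26 alternative settings and Ifi27 in 8 of 27. The gene model Gm15261, named after its values were seen, was the other (log2 fold change -2.88, edgeR adjusted p = 0.0416).

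**Figure D3:**
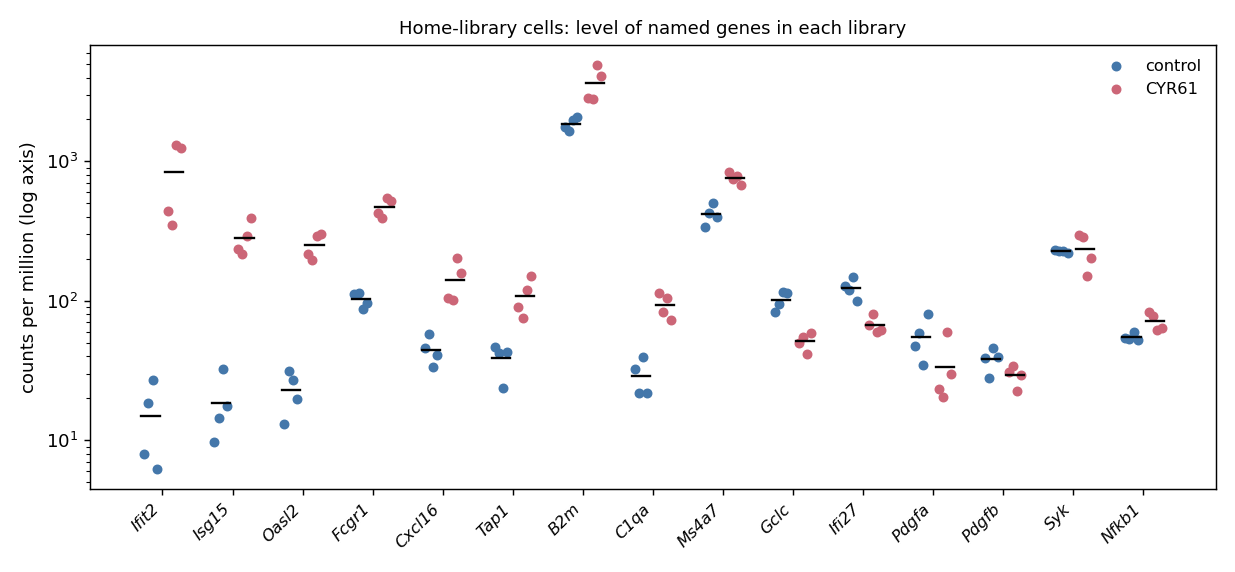
CPM (log axis) of named genes in home-library cells of each library, with points for the 4 control and 4 CYR61 libraries and lines for the group means. The groups do not overlap for the interferon response gene Oasl2 (22.8 against 252 CPM), and they overlap for Pdgfa, Pdgfb and Syk.

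Among lists with at least 3 measured members, the fixed type I interferon list moved most. In home-library cells 33 of its 34 members rose, 0 fell and 1 did not pass over all genes tested, and all 34 passed when adjusted over the list alone. The median log2 fold change was 3.57, with 2.88 at the earlier date alone and 3.89 at the later date alone. Isg15, a ubiquitin-like modifier (chromosome 4, 156199424 to 156200818), rose from 18.5 ± 9.69 to 284 ± 78.1 CPM (log2 fold change 4.05, SE 0.35, edgeR adjusted p = 8.47e-05, n = 4). Oasl2, an antiviral relative of the oligoadenylate synthetases (chromosome 5, 114896936 to 114912234), rose from 22.8 ± 8.04 to 252 ± 52.5 CPM (log2 fold change 3.51). Mean log2 CPM of the list was 6.99 ± 0.446 in CYR61 and 3.43 ± 0.233 in control libraries (exact two-sided permutation p = 0.0286, n = 4). The list passed the camera test (adjusted p = 5.20e-78) and was the sole list that also passed with an estimated correlation (adjusted p = 0.00895).

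**Figure D4:**
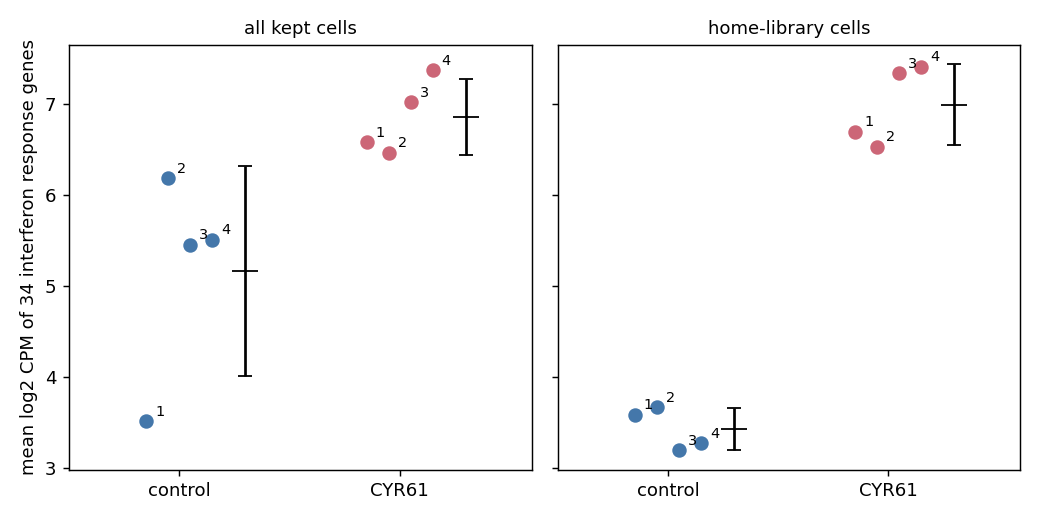
Mean log2 CPM of the 34 genes of the type I interferon list (vertical axis) per library, for all kept cells and for home-library cells. Points are libraries with their replicate numbers and bars are mean ± SD. In home-library cells the control libraries lie between 3.20 and 3.67 and the CYR61 libraries between 6.53 and 7.41.

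The lists of inflammatory mediators passed camera upward in home-library cells, and none passed with an estimated correlation (adjusted p from 0.110 to 0.112). The inflammatory cytokine and enzyme list had 3 of 7 measured members up and 0 down, and 3 up when adjusted over the list alone (median 0.59, camera adjusted p = 3.49e-06, adjusted p = 0.110 with an estimated correlation). Besides Acod1, they were Il1b, which encodes interleukin 1 beta (chromosome 2, 129364570 to 129371139), and Saa3, an acute phase protein (chromosome 7, 46711998 to 46715700). Il1b had 2 control counts and a ratio of 37.2 (10.2 to 308), and Saa3 rose from 1.88 ± 3.56 to 37.9 ± 20.2 CPM (log2 fold change 4.42, SE 0.84, edgeR adjusted p = 0.0197, n = 4). Among chemokines, 2 of 10 rose and 3 did when adjusted over the list alone (median 0.71, camera adjusted p = 0.000417, adjusted p = 0.110 with an estimated correlation). Cxcl16, a membrane-bound chemokine (chromosome 11, 70453983 to 70459984), rose from 44.4 ± 10.2 to 142 ± 48.3 CPM, and Ccl5, which attracts T cells (chromosome 11, 83525778 to 83530518), from 2.08 ± 3.96 to 41.6 ± 17.03 CPM. The NF-kB list had 0 of 26 members up or down, also when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.0122, adjusted p = 0.112 with an estimated correlation).

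Both antigen presentation lists passed camera upward, and neither did with an estimated correlation. Of 14 MHC class I genes 3 rose, and 11 did when adjusted over the list alone (median 0.99, camera adjusted p = 1.51e-12, adjusted p = 0.110 with an estimated correlation). B2m, the light chain of MHC class I (chromosome 2, 122147686 to 122153083), rose from 1866 ± 195 to 3672 ± 1024 CPM (log2 fold change 0.98, SE 0.20, edgeR adjusted p = 0.0385, n = 4), and kept its call in 18 of 27 alternative settings. Tap1, a subunit of the peptide transporter (chromosome 17, 34187553 to 34197225), and Tapbp, its partner tapasin (chromosome 17, 33915899 to 33929292), rose by log2 fold changes of 1.45 and 1.11. No MHC class II gene of 8 passed over all genes and 5 did when adjusted over the list alone (median 1.26, camera adjusted p = 0.000122, adjusted p = 0.104 with an estimated correlation).

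The macrophage and monocyte lists held a few large changes among many small ones. Of 25 mature macrophage genes 3 rose, also when adjusted over the list alone (median 0.30, camera adjusted p = 8.16e-06, adjusted p = 0.104 with an estimated correlation). C1qa (chromosome 4, 136895917 to 136898803) rose from 28.8 ± 8.72 to 93.8 ± 18.6 CPM. Ms4a7, a membrane protein of mature macrophages (chromosome 19, 11321039 to 11336146), rose by a log2 fold change of 0.87, and Marco, a scavenger receptor (chromosome 1, 120474538 to 120505024), by 3.86. Of 14 macrophage markers 3 rose and 5 did when adjusted over the list alone (median 0.30, camera adjusted p = 1.75e-06, adjusted p = 0.104 with an estimated correlation). Of 14 inflammatory monocyte genes 2 rose, Ms4a4c and Ms4a6c, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.00228, adjusted p = 0.112 with an estimated correlation). Ms4a6c (chromosome 19, 11469366 to 11482192) rose from 127 ± 37.7 to 486 ± 50.9 CPM. The 10 monocyte markers shared this pair, and their median was -0.04 while their mean was 1.07 and the test pointed up (camera adjusted p = 0.000893, adjusted p = 0.172 with an estimated correlation). The lysosome list had 0 of 24 up, and 3 when adjusted over the list alone (median 0.18, camera adjusted p = 0.0126, adjusted p = 0.404 with an estimated correlation).

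SYK, NF-kB and PDGF genes were followed by purpose, since the series title names them. The RNA level of a gene does not measure the activity of its protein, so these values do not test signalling. In simulated home-library counts the test recovered 12% of genes changed 2-fold. Syk, the kinase downstream of Fc receptors and integrins, was 234 ± 69.1 CPM with CYR61 and 227 ± 4.38 CPM in control in home-library cells (log2 fold change 0.05, SE 0.21, edgeR adjusted p = 0.9999, n = 4). Pdgfa and Pdgfb, which encode growth factors for stellate cells, did not pass. Pdgfa was 33.3 ± 17.96 against 55.1 ± 19.3 CPM (log2 fold change -0.79, SE 0.36, edgeR adjusted p = 0.807, n = 4), and Pdgfb had a log2 fold change of -0.36 (edgeR adjusted p = 0.962). Nfkb1, a subunit of NF-kB, was 71.3 ± 10.4 against 54.7 ± 3.30 CPM, without overlap but without passing (log2 fold change 0.39, edgeR adjusted p = 0.847, n = 4). The log2 fold changes of Rela, another subunit, and Irak4, a kinase of Toll-like receptor signalling, were 0.03 and -0.06. Those of the integrin genes Itgam and Itgb3 were 0.01 and -0.48, and that of Tlr4, the endotoxin receptor, was 0.17. In all kept cells the log2 fold changes were 0.03 for Syk, -0.48 for Pdgfa, -0.36 for Pdgfb and 0.24 for Nfkb1, with an edgeR adjusted p of 0.9999 for each of the 9 tested genes. Ccn1 itself had 0 counts in control cells and 1 count in CYR61 cells, too few for the main test. Without a gene filter it did not pass (log2 fold change 1.28 in all kept cells and 1.23 in home-library cells, edgeR adjusted p = 0.852 and 0.719).

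Of the SYK, PDGF, fibrosis and integrin lists, the first alone passed camera. Of 24 SYK and ITAM genes 2 rose in home-library cells, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.000893, adjusted p = 0.103 with an estimated correlation). Both were antibody receptors, Fcgr1 (chromosome 3, 96282909 to 96293969), from 103 ± 12.6 to 470 ± 70.7 CPM, and Fcgr4 (chromosome 1, 171018920 to 171029761), from 81.9 ± 14.9 to 192 ± 12.1 CPM. Among 3 measured PDGF genes, Pdgfc (chromosome 3, 81036416 to 81214040), a further PDGF ligand, had 2 control counts and 361 CYR61 counts, a ratio of 43.4 (11.9 to 360, edgeR adjusted p = 0.00686). It was the 1 PDGF gene that passed, also when adjusted over the list alone, and the list did not pass camera (median -0.36, mean 1.31, camera adjusted p = 0.792). The list passed fry upward (adjusted p = 0.00518), a test that does not compare a list with other genes. Of 24 fibrosis-associated macrophage genes Mmp13, a collagenase (chromosome 9, 7272514 to 7283331), rose from 24.99 ± 11.1 to 80.7 ± 21.8 CPM, while 5 rose and 1 fell when adjusted over the list alone. That list's median was -0.05 and its mean 0.13, and the test, which pointed up, did not pass (camera adjusted p = 0.792). The 15 integrins and other CCN1-binding proteins had a median of -0.05 and a mean of 0.11, and the test pointed down without passing (camera adjusted p = 0.792).

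Of 31 lists tested in home-library cells, 12 passed camera upward and 2 downward. With the Xist and Y split as a block 12 passed upward and 6 downward, and with the replicate block 12 and 0. With an estimated correlation the interferon list alone passed in the split fit (adjusted p = 0.0298), and the other 17 lists did not (adjusted p from 0.0546 to 0.735). Those down in the main fit were NRF2 targets and mitochondrially encoded genes. The NRF2 target list had Gclc down among 17 genes, and 2 down when adjusted over the list alone (median -0.15, camera adjusted p = 0.0236, adjusted p = 0.525 with an estimated correlation). The 8 mitochondrially encoded genes had a median of -0.36 (camera adjusted p = 0.0456, adjusted p = 0.511 with an estimated correlation). Lists of cell maintenance did not pass in the main fit. Their medians were -0.16 for glycolysis and hypoxia, -0.01 for oxidative phosphorylation, -0.17 for cholesterol synthesis and 0.12 for LXR targets. They were -0.27 for proliferation, 0.07 for immediate early genes, -0.09 for the unfolded protein response and -0.01 for iron handling. They were -0.11 for alternative activation, 0.11 for osteoclast differentiation and -0.14 for ribosomal proteins. The camera adjusted p of these lists ranged from 0.0638 to 0.925. With the Xist and Y split as a block, 4 of them passed downward, namely proliferation (camera adjusted p = 0.0149), ribosomal proteins (0.0230), unfolded protein response (0.0295) and glycolysis and hypoxia (0.0483). With an estimated correlation in that fit, none of the 4 passed (adjusted p from 0.166 to 0.735). Neutrophil markers (median 0.03, mean -0.04, camera adjusted p = 0.452), megakaryocyte markers (median 0.03, mean -0.02) and plasmacytoid dendritic cell markers (median 0.54, camera adjusted p = 0.0638) did not pass either, although Bst2, which tethers virions to cells and is also in the interferon list, rose by a log2 fold change of 2.23. YAP and TEAD targets and the markers of progenitors, dendritic cells, B cells, T or NK cells, eosinophils, erythroid and endothelial cells had under 3 measured members and were not tested. Among those, Ifi205 and Ccl5 rose and Ighm fell. Mast cell and stromal markers had 0 measured members.

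In all kept cells 14 of 31 tested lists passed camera, 11 up and 3 down, and 0 did with an estimated correlation. The medians of those up were 1.51 for interferon response, 0.78 for MHC class II, 0.60 for MHC class I, 0.62 for inflammatory cytokines, 0.45 for chemokines, 0.12 for SYK and ITAM and 0.21 for NF-kB. They were 0.25 for inflammatory monocyte genes, 0.18 for mature macrophage genes, 0.19 for macrophage markers and 0.28 for monocyte markers. With an estimated correlation each of these 11 had an adjusted p = 0.190. Those down were NRF2 targets (median -0.14, adjusted p = 0.519 with an estimated correlation), mitochondrially encoded genes (-0.26, adjusted p = 0.460 with an estimated correlation) and ribosomal proteins (-0.15, adjusted p = 0.844 with an estimated correlation). No list member passed over all genes in the edgeR fit of all kept cells, while DESeq2 called the list member C1qa. In macrophage- and monocyte-like cells 11 of 26 lists passed, 9 up and 2 down, and 0 did with an estimated correlation.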

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

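The tests of the home-library cells, of shared barcodes, of Xist, of the home library's choice, of a contaminant, and of other splits of home-library cells were chosen only after the result was seen.

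Barcodes recurred between libraries of the same date. If they coincided by chance, the other date would hold them about as often, but 91.9% of deep barcodes were listed in another library of the same date and 0.222% in one of the other date. Xist and Y-linked counts can check only copies between libraries that differ in them, which were 313 kept copies. Copies among control replicate 2 and CYR61 replicates 1 and 2, all Xist libraries, could not be checked. These hold the 75.5% of UMIs in control replicate 2. Of 123 informative copies between libraries that differ, 113 (91.9%, 95% Wilson interval 85.7% to 95.5%) carried the signal of the library with most UMIs. This is consistent with molecules or reads of a library being counted in another library of the same date. Whether that happened at pooling, sequencing or demultiplexing stays open, and no biological explanation was tested.

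Xist was the signal found outside the main measurement, at 1249 and 1213 CPM in home-library cells of control replicates 2 and 3 and at 1206 and 1152 CPM in those of CYR61 replicates 1 and 2, in animals labelled male. Copies from other libraries are argued against by the lowest of these values, 1152 CPM, since home-library cells should then lack Xist. Cells of both sexes pooled in each library are argued against by 0 of 1387 deep cells with Y-linked UMIs and no Xist, which allows a share of up to 0.216% over these 4 libraries together (3 cells of the total). Of these cells, 453 and 856 came from CYR61 replicates 1 and 2 and 47 and 31 from control replicates 2 and 3, so the count says little on each control alone. There the Y-linked genes summed to 1.70 and 8.31 CPM, against 323 CPM or more in the Y libraries. In every library the lower of the Xist and Y-linked signals was at most 0.685% of the higher. Animals of different sexes would give this, and so would an exchange with libraries of female cells from outside the series. The values do not separate these. An exchange among libraries of male cells alone would not give Xist. The sex of the animals thus stays open as an untested biological difference between libraries of each group.

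Interferon response genes were higher in CYR61 home-library cells. A difference in depth or cell number was examined with equal numbers of thinned cells. The median log2 fold change of the 14 list members measured was 3.07, against 3.08 for the same genes before. Random thinning keeps the expected proportions of genes, so a similar median was likely in advance and does not decide this. All 14 were still called up, so their calls did not need the unequal depth. The other list members were too low to be measured there. The choice of the home library is argued against by barcodes listed in a single table, where the median over 29 members was 3.35 against 3.51. A contaminant of the added protein, such as endotoxin, cannot be told apart from the protein, since 3 of 7 members of the inflammatory cytokine list passed upward, which either could raise. None of the 26 NF-kB list members passed, and at 2-fold the simulated test found few changes. Both a response to CYR61 and a contaminant therefore stay open.

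Other splits of the 8 libraries into 4 and 4 were counted for each gene test. In all kept cells and in macrophage-like cells the real count was 0, which all 35 splits reach whatever the data, so the count decides nothing there. The highest other counts were 2814 and 2800 genes. In home-library cells 2 of 35 splits gave at least the real 121 genes, so chance was not excluded. In each of these 3 sets the highest count came from the split that parts the Xist libraries from the Y libraries (1096 genes in home-library cells), which points to a structure of the samples. With that split as a block the real count was 231 and 1 of 18 splits, the real one, reached it, with 22 as the highest other. These 18 splits are too few for a share under 0.05.

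The effect of CYR61 in home-library cells differed between the Xist and the Y libraries for 5 of 10422 genes in the edgeR interaction test, with 1079 at an unadjusted p under 0.05. All 5 had the larger log2 fold change in the Y libraries, and they were named after their values were seen. The differences were 3.25 for Ifit2, 2.36 for Rtp4, a chaperone of taste receptors induced by interferon, 4.52 for Mcemp1, 1.71 for the chemokine Ccl9 and 3.14 for the gene model Gm21399 (adjusted p from 0.0069 to 0.0453). The interaction with the date called 0 genes in the same cells, with 1055 at an unadjusted p under 0.05 (smallest adjusted p = 0.207). The date stamp is uneven across these sets, since both CYR61 Xist libraries share a date and both CYR61 Y libraries share the other. The Xist libraries also had higher ribosomal RNA and mitochondrial shares than the Y libraries.

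Single libraries far from the rest of their group numbered 11 among 112 groups tested, where chance gives about 1 in 20. These flags are not independent, since macrophage and neutrophil shares of a library mirror each other. Genes with 1 to 3 control counts, such as Ifi206, Acod1, Ms4a4c and Ifi44, are flagged almost whenever a single library holds most of them. The number of flags is therefore no evidence of an excess. Control replicate 1 held 1058 home-library cells, above the other controls. CYR61 replicate 3 had 92.7% macrophage- or monocyte-like cells and 7.10% neutrophil-like cells, and CYR61 replicate 4 had 0% megakaryocyte-like cells. Control replicate 1 was alone with counts of Ifi206 (0.285 CPM) and of Acod1 (0.285 CPM) in home-library cells. Control replicate 3 was highest for Ms4a4c (2.48 CPM) and control replicate 4 for Ifi44 (3.12 CPM). Control replicate 2, the library with the largest share of barcodes from elsewhere, was highest for Saa3 (7.22 CPM), Ccl5 (8.02 CPM) and Ms4a6c (183 CPM).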

How the results depend on the processing

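The settings with home-library cells, the Xist and Y split, single-table barcodes, equal cells and ribosomal RNA left out were chosen only after the data were seen.

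In all kept cells edgeR called 0 genes in every alternative except the later date alone, with 56 (52 up, 4 down), the fit without a gene filter, with 118 (17 of them down), and home-library cells, with 121. DESeq2 called 1. In macrophage-like cells the counts were 51 in the later date alone, 119 without a filter, 2 with DESeq2 and 119 in home-library cells. The cause of these changes was not tested. Of the 117 genes that rose in home-library cells, 90 were also called up in all kept cells without a filter and 49 in the later date alone.

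Home-library cells gave 184 calls with DESeq2, 239 without a filter, 231 with the Xist and Y split as a block and 287 with the split and the date. The Xist libraries alone gave 371 (132 up, 239 down) and the Y libraries alone 196 (174 up, 22 down), each over 4 libraries, and the cause was not tested. Equal numbers of thinned cells gave 44 calls among 2446 genes tested, fewer genes by construction.

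Leaving out each library in turn gave 0 calls throughout in all kept cells, 0 to 5 in macrophage-like cells (5 without control replicate 2) and 74 to 127 in home-library cells (74 without CYR61 replicate 4, 127 without CYR61 replicate 3). Lists passing camera ranged from 11 to 15, 9 to 12 and 12 to 16. The difference in macrophage share ranged from -1.83 to 0.370 percentage points and that in neutrophil share from -0.308 to 1.89, each changing sign without CYR61 replicate 3. The megakaryocyte difference ranged from -0.100 to 0.0336, positive without control replicate 4. With all barcodes the macrophage difference was 0.445 and the neutrophil difference -0.06, and the cause was not tested. No share passed in any setting.

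With an estimated correlation 0 lists passed in all kept cells, 0 in macrophage-like cells and 1, interferon response, in home-library cells. Fry called 1 list in all kept cells and 1 in macrophage-like cells, the unfolded protein response, downward in both. In home-library cells it called 10 lists upward, namely interferon response, SYK and ITAM, PDGF, inflammatory cytokines, chemokines, MHC class I, MHC class II, inflammatory monocytes, mature macrophages and macrophage markers.

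Replicate numbers gave no steady pairing of the libraries. Same-numbered libraries had correlations of -0.18, 0.71, 0.01 and 0.27 in kept cells and of -0.20, 0.32, -0.09 and 0.31 in home-library cells. In kept cells of control replicate 2, 40.6% of UMIs belonged to barcodes with most UMIs in CYR61 replicate 2. The 0.71 therefore includes shared barcodes, and the values do not exclude that some replicates were paired. With the replicate block edgeR called 0 genes in all kept cells, 0 in macrophage-like cells and 112 in home-library cells.

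Among the 13 genes named by rule in home-library cells, 288 of 329 values in alternatives kept their call, 41 lost it and 0 reversed, and 9 genes kept it throughout. Among the genes named from lists, the call was lost for B2m in 9 of 27 settings, Marco in 9 of 23, Ms4a7 in 8 of 27, Tap1 in 7 of 26 and Tapbp in 5 of 27. It was lost in 6 settings each for Il1b (of 19), Saa3 (of 24), Ccl5 (of 26) and Mmp13 (of 26). No gene followed by purpose passed in any setting. Fits of other classes, and of the difference between classes with their replicate block, were not run because no other class had 20 cells in every library. Depth limits the rarest genes, and at 2-fold the simulated test found few changes.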

Other observations

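The counts of genes in and outside the fixed lists were chosen only after the result was seen.

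Of the 117 genes that rose in home-library cells, 50 were in a fixed list, 33 of them in the interferon list, and 67 were in none. The 67 are not all apart from the interferon response, since the interferon-inducible Ly6e is among them. The examples below were picked from these 67 after their values were seen. Gbp2, Gbp3 and Gbp7, guanylate-binding proteins that attack vacuoles of intracellular microbes, had log2 fold changes of 2.59, 3.86 and 2.52. Irgm1 and Irgm2, immunity-related GTPases, had values of 2.45 and 1.79. Slfn1, Slfn2, Slfn3, Slfn4 and Slfn8, Schlafen genes linked to growth control, rose by 5.45, 1.61, 2.24, 4.87 and 2.27. Ifitm3, which blocks viral entry, went from 83.3 ± 28.4 to 749.6 ± 411 CPM, and Ly6e from 76.5 ± 30.02 to 640.3 ± 290 CPM (edgeR adjusted p = 0.000962 and 0.000531, n = 4). Parp9, Parp12 and Parp14, ADP-ribosyltransferases, had log2 fold changes of 1.66, 1.51 and 1.99. Genes with no such family among them included Npy, a neuropeptide (1.05), Lgals3bp, a secreted glycoprotein (1.73), Lgals9, a galectin (1.40), and Aif1, an actin-binding protein of macrophages (1.21).

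Kept cells also held a cluster of 796 cells led by Top2a and Mki67, genes of dividing cells, within the macrophage-like class. It held 227 cells of control replicate 2, 189 of CYR61 replicate 1 and 294 of CYR61 replicate 2. A cluster of 44 cells was led by Vcam1, an adhesion molecule, and stayed in that class. Its cells came only from the same libraries, with 12, 14 and 18 cells. These libraries share many barcodes, so a barcode can be counted more than once in either cluster.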
